A study of Mus musculus with 6 samples.

How the data were processed

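Per the labels' protocols, oligo(dT) beads captured the poly(A) RNA of the sorted DsRed-positive stroma, and 6% of it was saved as Input. The rest was incubated for 2 h with protein A/G beads that had been bound for 1 h with 1.25 micrograms of antibody to m6A or of IgG. After washes of low salt, high salt and detergent, the bound RNA was eluted for 1 h with free N6-methyladenosine monophosphate. Libraries were made by the Smart-seq2 method, which copies full-length polyadenylated RNA with oligo(dT) priming and amplifies it before tagmentation, without molecular identifiers and without marking strand. A gene with 0 counts in a library made from a small eluate is not shown to be absent from the RNA. Unbound fractions were not used here.

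The authors deposited 1 table of raw counts per gene, with Entrez gene numbers in rows and the 6 libraries in columns. The submitters' processing notes name Picard, featureCounts, edgeR 3.38.1 and the mouse build mm10, without the role or order of the tools; the aligner and the annotation are not given in the sources used here. Each column was matched to a sample by its name. Of 27179 gene numbers, 25275 matched a symbol in the RefSeq table of GRCm38.p6 (the assembly that mm10 names), and 1904 did not and carried 0.722% to 1.38% of the counts of a library; they stayed in the fits under their number. At 0 in all 6 libraries were 12754 genes. Coordinates are 1-based positions of the gene on GRCm38. Reads of overlapping or antisense genes cannot be told apart without strand.

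Groups and replicate numbers were taken from the sample titles, with 2 libraries in each of the 3 groups. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with groups, a minimum count of 10 and a minimum total of 15, which left 11281, and libraries were scaled by TMM. All 6 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with 3 group means and 3 residual degrees of freedom, so that the groups shared 1 estimate of the spread per gene. The dispersion trends set for the simulations below had medians of 0.87 in Input, 0.74 in IgG and 0.026 in anti-m6A. Genes at 0 in a pair were given the largest value of that pair's trend. At least 7224 of the 11281 genes were at 0 in both IgG libraries, so the IgG median is this assigned value. Over genes with at least 20 counts in a pair, the measured spread was 119 times random sampling in Input, 21.9 in IgG and 9.93 in anti-m6A. Each SE and p-value thus averages over unlike pairs. The 3 contrasts were anti-m6A against IgG, anti-m6A against Input and IgG against Input. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Genes higher in anti-m6A than in both other groups were called from the larger of both one-sided p-values, adjusted likewise. The SE of a log2 change is its size divided by the square root of the F statistic. CPM values are counts scaled to the TMM-adjusted library size.

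A group with 0 counts in both libraries gives no fold, so the other group's mean CPM was divided by the mean CPM that 3 counts per library stand for, and the result is written as at least so many fold. The floor was 0.355 and 0.291 CPM in Input, 1.16 and 1.94 CPM in IgG and 0.622 and 0.756 CPM in anti-m6A. Fitted log2 values of such genes depend on edgeR's prior count and are given only within medians and means over genes. Where setting such genes to their bound moves a reported median of a list, that median is given too, and means and the median of all genes are of fitted values.

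There were 22 gene lists: m6A writers, erasers and readers; transcripts reported as m6A-methylated in other cell types; HSC niche factors and stromal progenitor markers; osteogenic, chondrogenic and adipogenic genes; the KLF family; immediate early genes; cytosolic ribosomal proteins; nuclear-encoded oxidative phosphorylation subunits; mitochondrially encoded genes, of which the table holds the ribosomal RNAs; Zfp zinc finger genes; collagens; replication-dependent histones; chromatin and transcription regulators; genes of the NOTCH, WNT, BMP and hedgehog pathways; cell cycle genes; and markers of blood, endothelium, pericytes and muscle, osteoclasts, and Schwann and neural cells. Each was tested against the other genes with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests a list by itself, were run beside it. No list passed 0.05 with an estimated correlation in any of the 3 comparisons. That form of camera rests on the 3 residual degrees of freedom and so has little power here. For histones in anti-m6A against Input the estimated correlation was -0.00051, below the preset 0.01, yet the camera adjusted p went from 0.0332 to 0.865. Losing a call there does not by itself show that correlation between genes made it.

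The tests, the lists and the rule for named genes were chosen before the data were examined. The rule takes the 10 genes with the largest log2 change in each direction among genes past the threshold, with an average log2 CPM of at least 3 and both anti-m6A libraries on the same side of both libraries of the other group (5 per direction for IgG against Input). Predicted or unnamed genes and pseudogenes were passed over. Klf2 and Mettl3 were fixed by name, and up to 4 members per list with the smallest p against IgG were taken. Cxcl12, Kitl, Angpt1, Lepr and Malat1, and members named because few in a list were called, were chosen after their values were seen.

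The alternatives planned were DESeq2's size factors in the same fit, library totals alone, no count filter, at least 50 counts in 2 libraries, DESeq2 1.42.0, the replicate number as a block, only the libraries of the groups compared, an adjusted p of 0.01, a minimum fold of 1.5 and leaving out each library in turn. Genes with at least 10 counts in each library, and each pull-down pair summed to 1 library, were added after seeing the data. No samples of other series were in the table, and no library was left out of the main comparisons.

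The fit was tested on simulated counts for the 11281 genes with the real means and library sizes, with a dispersion trend taken from each pair of libraries and 200 genes changed, 40 for each fold. For anti-m6A against IgG the fit recovered 0% of 2-fold, 0% of 4-fold, 15% of 16-fold, 35% of 64-fold and 67.5% of 256-fold changes, with 0 unchanged genes called. For anti-m6A against Input it recovered 0%, 5%, 15%, 42.5% and 45% of the same folds, with 1 unchanged gene called, and for IgG against Input 0%, 0%, 15%, 27.5% and 40%, with 0 called. The dispersion model and the larger folds were set after first simulations, with smaller folds, recovered few genes. Recovery after adjustment depends on how many genes change, so these shares hold for the simulation and not for the real libraries. A gene that was not called is not shown to be equal.

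Transcript length, GC content and the density of the DRACH motif (the sequence context of m6A) in the 3' UTR were taken from the longest protein-coding transcript of each gene in GENCODE M21. Random gene lists for the length test were drawn 10000 times from the 50 nearest genes of each member.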

Results

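RNA was measured in stromal cells of the bone marrow of P2 mice of the C57BL/6 strain. The cells were sorted for the red fluorescent reporter DsRed placed in the Cxcl12 gene, and cells carrying markers of blood, erythroid or endothelial cells were left out of the sort. Cxcl12 encodes the chemokine that holds haematopoietic stem cells (HSCs) in their niche. Poly(A) RNA was incubated with beads carrying an antibody to N6-methyladenosine (m6A), the most common internal base modification of mRNA, or with beads carrying IgG as background control. The labels state no fragmentation before the pull-down, and counts are summed per gene, so they do not locate a methylated site. There were 2 Input libraries (6% of the RNA, set aside before the pull-down), 2 IgG-bound libraries and 2 libraries bound by the m6A antibody (anti-m6A).

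The deposited counts summed to 7125578 and 9493391 in the Input libraries, 2487148 and 1278735 in the IgG libraries and 6102070 and 5133237 in the anti-m6A libraries. Input held 10024 and 11186 detected genes, IgG 3266 and 2723, and anti-m6A 12714 and 12391. Genes found in both libraries of a group numbered 9697 for Input, 2613 for IgG and 12062 for anti-m6A. Over genes with at least 20 counts in a pair, the replicates differed by 119 times the variance of random sampling in Input, 21.9 times in IgG and 9.93 times in anti-m6A. The labels do not say that replicates came from separate animals or pull-downs, so p-values measure the spread between these libraries, which may be technical.

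**Figure D1:**
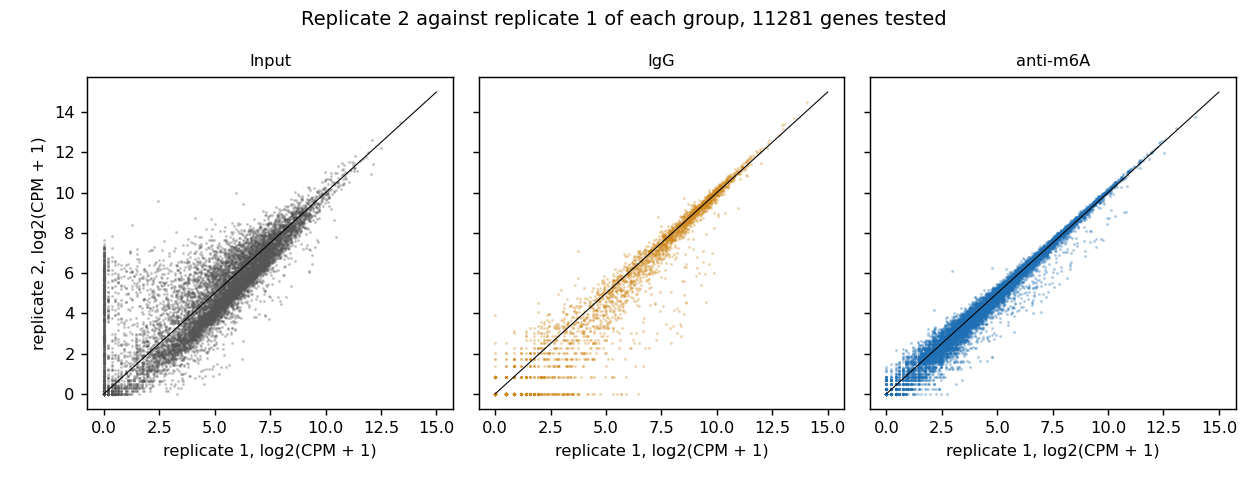
Each point is 1 of the 11281 genes tested, with log2(CPM + 1) from library totals in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, for the Input, IgG and anti-m6A pairs; the line marks equal values. The Input pair scatters most widely, with variance 119 times that of random sampling, against 21.9 times for IgG and 9.93 times for anti-m6A.

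The comparison of anti-m6A with IgG asked which transcripts the m6A antibody recovered beyond the background antibody. The 10 largest increases were Sub1 (a transcriptional coactivator), Copz2 (a coatomer subunit), Tubb5 (a beta-tubulin), Ccdc124, Ndufb10 and Ndufb11 (subunits of respiratory complex I), Bex3, Igf1 (insulin-like growth factor 1), Hsp90ab1 (a chaperone) and Dynlrb1 (a dynein light chain), each with 0 counts in both IgG libraries. Sub1 reached 2668 ± 205 CPM (normalised counts scaled to library size; SD, n = 2) in anti-m6A, at least 1719-fold above the IgG floor of 3 counts per library. Igf1 (chromosome 10, 87858265 to 87937047) reached 1747 ± 92.1 CPM (SD, n = 2), at least 1126-fold higher. The 10 largest decreases were Gnmt, Gc (vitamin D-binding protein), Agxt, Ugt2b36, Cyp2c70, Ces3a and Cpb2, all known for high expression in liver, with S100a8 (a neutrophil calcium-binding protein), Atic (a purine synthesis enzyme) and Wfdc21, each with 0 counts in both anti-m6A libraries. Agxt stood at 1406 ± 35.9 CPM (SD, n = 2) in IgG, at least 2040-fold above the anti-m6A floor.

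By edgeR's quasi-likelihood test at an adjusted p of 0.05, 8249 of 11281 genes were higher in anti-m6A than in IgG and 938 were lower. Of the higher genes, 7224 had 0 counts in both IgG libraries. Among the 1757 genes with at least 10 counts in each library the test called 593 higher and 586 lower, and with each pull-down pair summed to 1 library, a fit that takes its whole spread from the Input pair, it called 5486 and 572. Of the 10 largest decreases, Gc, Ugt2b36, Wfdc21 and Ces3a were no longer called when either IgG library was left out (edgeR adjusted p from 0.0566 to 0.0881).

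A list of 40 hepatocyte transcripts, written after the gene tables were seen, took 4.16% (exact 95% confidence interval 4.13 to 4.18) and 4.30% (4.27 to 4.34) of the counts in the IgG libraries. It took 0.157% (0.154 to 0.160) and 0.161% (0.158 to 0.165) in anti-m6A, and 0.0365% (0.0351 to 0.0379) and 0.456% (0.451 to 0.460) in Input. Members of the list differed: Ambp, Tdo2, Hpd, Bhmt, Asgr1 and Mat1a were at 0 in both IgG libraries and had counts in both anti-m6A libraries, and Apoh had 7 and 0 counts in IgG and 364 and 271 in anti-m6A. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Of 15 blood transcripts tested, 8 were lower in anti-m6A than in IgG and 1, Vpreb1 (a pre-B cell receptor chain), was higher. Hba-a2 (alpha-globin, which shares reads with its copy Hba-a1) fell by 1.98 ± 0.19 on the log2 scale (SE, n = 2 per group), and Mpo (myeloperoxidase), with 989 and 370 counts in IgG, was at 0 in the other libraries. As a list, blood transcripts were lower than other genes (camera adjusted p = 3.42e-08), with adjusted p = 0.467 with an estimated correlation and 0.123 among genes with at least 10 counts in each library. The 2 mitochondrial ribosomal RNAs, mt-Rnr1 and mt-Rnr2, were lower by log2 changes of -1.89 ± 0.31 and -1.94 ± 0.23 (SE, n = 2 per group); this list was called by camera (adjusted p = 0.0196), but not with an estimated correlation (adjusted p = 0.886) or among genes with at least 10 counts in each library (adjusted p = 0.366).

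**Figure D2:**
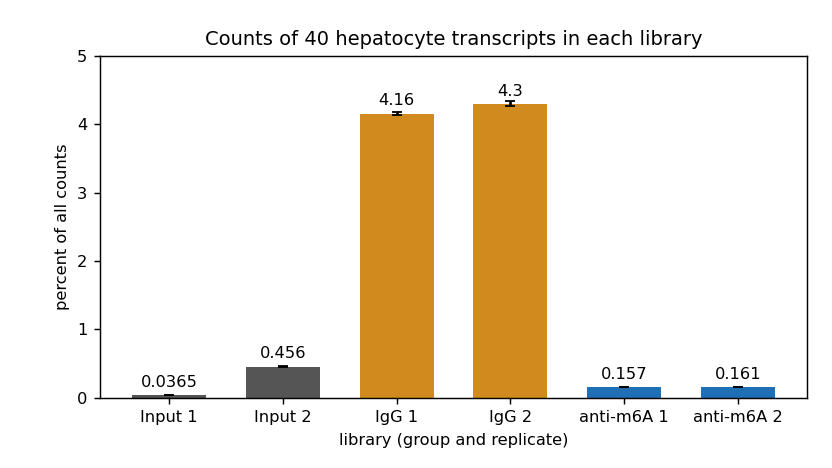
Bars give the percent of all counts in each of the 6 libraries that fell on 40 hepatocyte transcripts, with exact 95% confidence intervals for counting error. The IgG libraries stand at 4.16% and 4.30%, the anti-m6A libraries at 0.157% and 0.161%, and the Input libraries at 0.0365% and 0.456%.

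Of 24 HSC niche factors and stromal progenitor markers tested, 21 were higher in anti-m6A than in IgG and 1, Cxcl12, was lower. Prrx1, a mesenchymal transcription factor, was at least 139-fold higher, Csf1, the macrophage growth factor, at least 118-fold, and Ptn, pleiotrophin, at least 136-fold. The fitted median log2 change of the list was 8.90, and 4.82 with genes at 0 set to their bound. Cxcl12 itself (chromosome 6, 117168535 to 117181368) was abundant in each group, at 4604 ± 323 CPM in Input, 2709 ± 24.3 in IgG and 2101 ± 50.4 in anti-m6A (SD, n = 2 each). Its log2 change against IgG was -0.37 ± 0.12 (SE, n = 2 per group, edgeR adjusted p = 0.0348). The change was -0.37 (edgeR adjusted p = 0.0855) with the replicate number as a block, and -0.04 (adjusted p = 0.834) among genes with at least 10 counts in each library. The list rose relative to other genes (camera adjusted p = 0.0196), but not with an estimated correlation (adjusted p = 0.467). Nor did it with the replicate number as a block (camera adjusted p = 0.326) or among genes with at least 10 counts in each library (0.0936). The call was also lost when any 1 of the 6 libraries was left out, with medians from 8.41 to 9.29. The Cxcl12 call was lost without either IgG library (edgeR adjusted p = 0.0868 and 0.0619), without either anti-m6A library (0.184 and 0.169) and with DESeq2's size factors (0.121).

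Among the 22 genes that write, erase or read m6A, 18 were higher in anti-m6A than in IgG and 1 was lower. Of all 11281 genes tested 8249 were higher, and the list did not differ from other genes (camera adjusted p = 0.798). Mettl3 (chromosome 14, 52294841 to 52308741), the catalytic subunit of the m6A methyltransferase, had 55 and 23 counts in anti-m6A and 0 in both IgG libraries, at least 5.54-fold higher. The nuclear reader Ythdc1 was at least 204-fold higher. The demethylase Fto went the other way, at 26.5 ± 3.27 CPM in anti-m6A and 779 ± 121 in IgG (SD, n = 2 each), a log2 change of -4.87 ± 0.42 (SE). Klf2 (chromosome 8, 72319062 to 72321654), a zinc finger transcription factor, had 165 and 149 counts in anti-m6A and 0 in both IgG libraries, at least 23-fold higher.

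The remaining fixed lists were compared with IgG in the same way. Higher and lower members numbered 14 and 2 of 20 osteogenic genes, 5 and 0 of 6 chondrogenic, 13 and 2 of 16 adipogenic, 12 and 0 of 14 KLF family and 9 and 3 of 15 immediate early genes. Pathway genes of NOTCH, WNT, BMP and hedgehog gave 24 and 1 of 30, chromatin and transcription regulators 23 and 2 of 28, collagens 17 and 4 of 26, Zfp zinc finger genes 182 and 9 of 229 and cell cycle genes 7 and 2 of 15. Cytosolic ribosomal proteins gave 39 and 6 of 84, subunits of oxidative phosphorylation 43 and 7 of 77, and replication-dependent histones 13 and 6 of 25. Transcripts reported as m6A-methylated in other cell types gave 9 and 2 of 14. Markers of endothelium gave 6 and 0 of 9, of pericytes and muscle 5 and 0 of 9, of osteoclasts 3 and 0 of 3, and of Schwann and neural cells 2 and 0 of 2. None of these lists differed from the other genes in the camera test with the preset correlation (the smallest adjusted p was 0.0549, for ribosomal proteins). The ribosomal median was positive at 0.69, but the test placed the list below other genes. Among genes with at least 10 counts in each library the direction turned: ribosomal proteins (36 higher and 3 lower of 68) and oxidative phosphorylation subunits (39 and 6 of 61) were both higher than other genes (camera adjusted p = 0.00725 and 0.00126). Adjusted over the list alone, the counts of all lists were the same except for ribosomal proteins, with 36 and 4.

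The comparison of anti-m6A with Input asked which transcripts took a larger share after the pull-down than in the RNA put into it. The 10 largest increases were Isg20 (an RNA exonuclease induced by interferon), Nxt1 (an mRNA export cofactor), Gins2 (a DNA replication factor), Zfp286, Ccdc86, Srrd, Tmem126b (a complex I assembly factor), Anapc15 (a subunit of the anaphase-promoting complex), Adamts7 (a metalloprotease) and Xpo4 (an exportin), each with 0 counts in both Input libraries. Ccdc86 and Tmem126b were higher still in IgG, at 644 ± 43.5 and 553 ± 49.9 CPM against 130 ± 1.94 and 113 ± 0.874 in anti-m6A (SD, n = 2 each). Isg20 (chromosome 7, 78913396 to 78920396) reached 218 ± 18.3 CPM (SD, n = 2), at least 676-fold above the Input floor. Klf2 rose from 1.72 ± 1.75 CPM in Input to 35.9 ± 2.36 in anti-m6A (SD, n = 2 each), a log2 change of 4.37 ± 1.03 (SE; edgeR adjusted p = 0.0293); without either anti-m6A library its adjusted p was 0.144 and 0.161. Mettl3 stood at 11.9 ± 4.38 CPM in Input and 8.60 ± 3.97 in anti-m6A (SD, n = 2 each) and was not called (log2 change -0.47 ± 0.59 SE, edgeR adjusted p = 0.561). The 10 largest decreases were Scube1, Serpina1b (an alpha-1 antitrypsin with near-identical copies, so uncertain), Usp13 (a deubiquitinase), Ibtk, S100a8, Atic, Oxld1, Trim10, Cfap45 and Aldh1b1 (an aldehyde dehydrogenase), each with 0 counts in both anti-m6A libraries. Scube1 had 1327 and 849 counts in Input and was at least 174-fold lower in anti-m6A.

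By edgeR's quasi-likelihood test, 3156 genes were higher in anti-m6A than in Input and 2308 were lower, 57.8% higher among the calls. Of the higher genes, 1308 had 0 counts in both Input libraries, and 286 of the lower genes had 0 counts in both anti-m6A libraries. Loss of genes while the Input libraries were made was not separated from a rise in anti-m6A. With DESeq2's size factors in the same fit, which moved the median log2 change of all genes by -0.40, the split was 2711 and 2982, 47.6% higher, and with library totals alone, which moved it by -0.51, it was 2609 and 3127, 45.5% higher. With each pull-down pair summed there were 711 higher and 174 lower genes, without anti-m6A replicate 1 there were 370 and 72, and without replicate 2 there were 408 and 93. Leaving out Input replicate 2 gave 5152 and 3472, and leaving out Input replicate 1 gave 4730 and 3961. Of the 70 named genes called in this comparison, 30 were also called with the pairs summed, among them the 20 largest changes. Without anti-m6A replicate 1, 26 of 68 named genes were called, and without replicate 2, 28 of 69. Of the 20 largest changes Atic alone was lost in these fits (edgeR adjusted p = 0.0715 and 0.0510), and it was also lost without either IgG library (0.0965 and 0.0967).

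**Figure D3:**
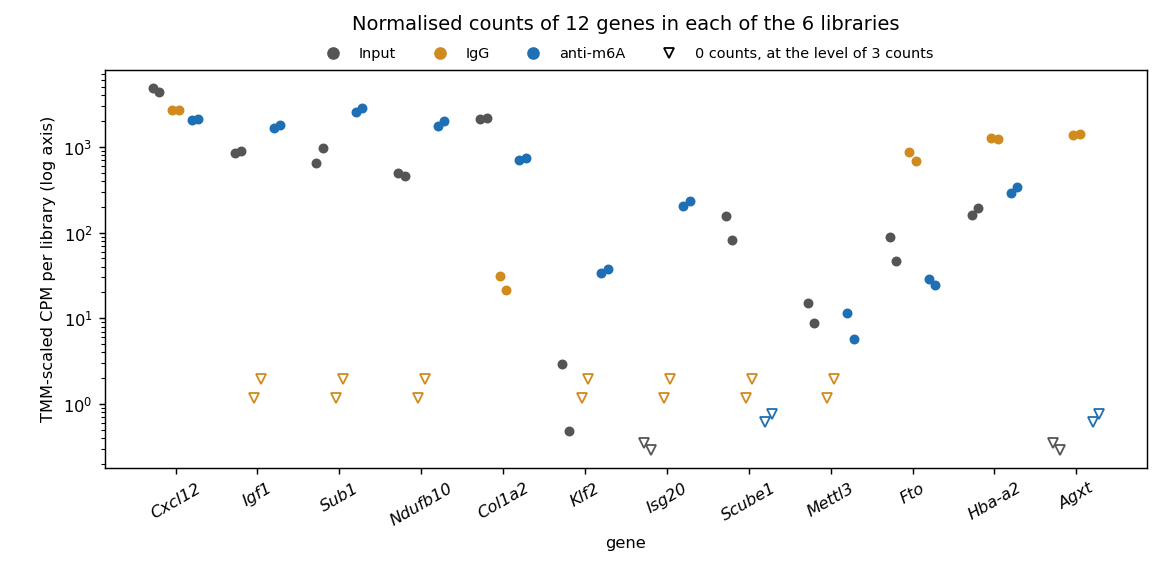
Points give the TMM-scaled CPM (log axis) of 12 genes in each of the 6 libraries, coloured by group; open triangles mark a library with 0 counts, drawn at the level that 3 counts would have in it. Igf1, Sub1, Ndufb10, Klf2 and Isg20 lie higher in both anti-m6A libraries than in Input and are at 0 in IgG, whereas Agxt has counts in the IgG libraries alone.

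Several HSC niche factors took a smaller share in anti-m6A than in Input. Of 24 niche and progenitor genes tested, 5 were lower, namely Cxcl12, Kitl (stem cell factor), Angpt1 (angiopoietin 1), Csf1 and Lepr (the leptin receptor, a marker of niche stroma), and 6 were higher, namely Igf1, Bmp4, Grem1, Prrx2, Thy1 and Ly6a. The log2 changes (SE, n = 2 per group) were -1.13 ± 0.12 for Cxcl12, -1.56 ± 0.28 for Kitl, -1.90 ± 0.30 for Angpt1, -0.98 ± 0.23 for Csf1 and -0.89 ± 0.25 for Lepr, against 1.00 ± 0.16 for Igf1. Igf1 was not called with library totals alone as scaling (log2 change 0.45, edgeR adjusted p = 0.0614). With the pairs summed, none of these 5 lower genes or Igf1 was called (edgeR adjusted p of 0.0517 for Cxcl12 and 0.120 to 0.378 for the others). Without either anti-m6A library Cxcl12 was still called, but Kitl, Angpt1, Csf1, Lepr and Igf1 were not (edgeR adjusted p from 0.107 to 0.352). The list as a whole did not differ from other genes (median -0.27, mean 0.82, camera adjusted p = 0.618).

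Of 77 nuclear-encoded subunits of oxidative phosphorylation, 54 were higher in anti-m6A than in Input and 5 were lower (Cox8b, Ndufa9, Ndufv1, Sdha and Uqcrc2). Ndufb10 rose by a log2 change of 1.97 ± 0.18 and Ndufb11 by 1.70 ± 0.17, while Ndufa9 fell by 1.27 ± 0.24 (SE, n = 2 per group). Without either anti-m6A library Ndufb10 was still called, but Ndufb11 (edgeR adjusted p = 0.0548 and 0.0620) and Ndufa9 (0.206 and 0.203) were not. The median of this list was 1.40 (camera adjusted p = 5.00e-04; adjusted p = 0.865 with an estimated correlation), and adjusted over the list alone the counts were 56 and 6. The median was 0.86 with library totals and 0.89 among genes with at least 10 counts in each library. Of 84 cytosolic ribosomal proteins, 32 were higher and 2, Rpl3 and Rpl4, were lower, with a median of 0.81 (camera adjusted p = 0.0125; adjusted p = 0.865 with an estimated correlation) and 29 and 2 adjusted over the list alone. The ribosomal call was lost with DESeq2's size factors (median 0.36, adjusted p = 0.177), with library totals (median 0.26, adjusted p = 0.310) and among genes with at least 10 counts in each library (median 0.26, adjusted p = 0.176). Of 25 replication-dependent histones, 14 were higher and 1, H2ac11, was lower, with a median of 2.28, or 2.15 with genes at 0 set to their bound (camera adjusted p = 0.0332; adjusted p = 0.865 with an estimated correlation), and 15 and 1 adjusted over the list alone. Histone genes have near-identical copies, so single members such as H2ac8, with 9 counts over both Input libraries and 528 over both anti-m6A libraries, are uncertain; H2ac8 was not called without either anti-m6A library (edgeR adjusted p = 0.0557 each). Of the 25 histones 7 had 0 counts in both Input libraries, and the median of their average log2 CPM was 2.20. The histone median was 1.29 without anti-m6A replicate 1, 1.499 without replicate 2 and 1.45 without a count filter. With the replicate number as a block the median was 2.28 and the list was not called (camera adjusted p = 0.0551). The camera call of histones was lost without Input replicate 1 (adjusted p = 0.203), Input replicate 2 (0.193) or anti-m6A replicate 1 (0.0660), without a count filter (0.0952), and among genes with at least 10 counts in each library (0.137).

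Of 26 collagens tested, 15 were lower in anti-m6A than in Input and 1, Col22a1, was higher, with a median log2 change of -1.09 (camera adjusted p = 0.00703; adjusted p = 0.865 with an estimated correlation); adjusted over the list alone, 16 were lower and 1 was higher. Col1a2, a chain of type I collagen, went from 2157 ± 64.4 to 719 ± 31.3 CPM (SD, n = 2 each), a log2 change of -1.58 ± 0.21 (SE), and Col3a1 and Col5a2 had log2 changes of -1.08 ± 0.22 and -1.09 ± 0.24 (SE). Col1a2 was not called without anti-m6A replicate 1 (edgeR adjusted p = 0.0567), nor were Col3a1 and Col5a2 without either anti-m6A library (0.224 to 0.249).

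Of 14 transcripts reported as m6A-methylated in other cell types, 3 were higher than Input (Malat1, Son and Btg2) and 4 were lower (Ep300, Myc, Socs3 and Xist); adjusted over the list alone, 4 and 4. Son, which encodes a splicing cofactor, rose by a log2 change of 1.71 ± 0.28 and the long noncoding RNA Malat1 by 0.69 ± 0.11 (SE, n = 2 per group), and Malat1 was not called with DESeq2's size factors (log2 change 0.25, edgeR adjusted p = 0.253) or without either anti-m6A library (0.0686 and 0.105). Of 22 m6A genes, 5 were higher (Ythdc1, Ythdc2, Virma, Cbll1 and Igf2bp3) and 5 were lower (Fto, Fmr1, Mettl16, Rbm15b and Ythdf3). Ythdc1 was not called with DESeq2's size factors (edgeR adjusted p = 0.0559), library totals (0.0812) or without either anti-m6A library (0.218 and 0.244), and Btg2 was not called without either anti-m6A library (0.207 and 0.308). Fto was not called without either anti-m6A library (edgeR adjusted p = 0.135 and 0.174) or either IgG library (0.0603 and 0.0592). With DESeq2's size factors Hnrnpc and Zc3h13 were also called lower (edgeR adjusted p = 0.0208 and 0.0175). In the KLF family 5 of 14 were higher (Klf2, Klf5, Klf7, Klf8 and Klf10) and none was lower; adjusted over the list alone, 4. Klf7 and Klf10 were not called with DESeq2's size factors (edgeR adjusted p = 0.126 and 0.0617) or without either anti-m6A library (0.243 to 0.527). Of 16 adipogenic genes, 7 were higher, among them the fatty acid-binding protein Fabp4 (log2 change 2.71 ± 0.32, SE) and the transcription factor Cebpb (2.94 ± 0.41), and 2, Cebpa and Lpl, were lower. Of 20 osteogenic genes, 4 were higher (Spp1, Sparc, Col22a1 and Bglap, which shares reads with its near-identical copy Bglap2) and 5 were lower, among them Col1a1 and Col1a2. Of 15 immediate early genes, 2 were higher (Atf3 and Nr4a2) and 6 were lower, among them Jun (log2 change -1.45 ± 0.36, SE), which was not called without either anti-m6A library (edgeR adjusted p = 0.203 and 0.240). The median of the m6A genes was -0.50 and their mean 0.04. None of these 6 lists differed from other genes in the camera test (adjusted p from 0.125 to 0.658).

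**Figure D4:**
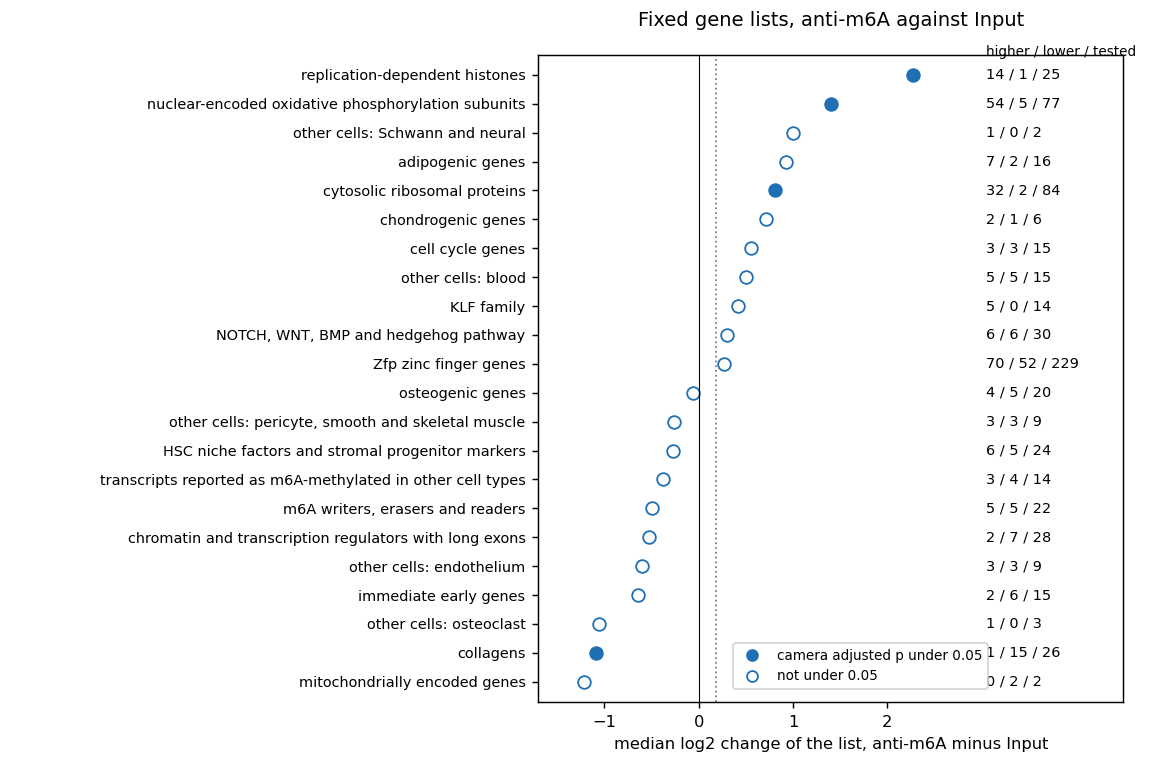
The horizontal axis gives the median log2 change of each of the 22 fixed gene lists, anti-m6A minus Input; filled points are lists called by camera with the preset correlation at an adjusted p of 0.05, and the dotted line is the median of all genes tested, 0.18. Numbers give members higher, lower and tested, for example 54, 5 and 77 for oxidative phosphorylation and 1, 15 and 26 for collagens; no call held with an estimated correlation.

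The other lists were not called by camera in this comparison (adjusted p from 0.385 to 0.947). Higher and lower members numbered 70 and 52 of 229 Zfp genes, 2 and 7 of 28 chromatin and transcription regulators with long exons, 6 and 6 of 30 pathway genes, 3 and 3 of 15 cell cycle genes and 2 and 1 of 6 chondrogenic genes. The BMP targets Id2 and Id3, the transcription factors Lef1 and Tcf7l2 and the BMP signal transducers Smad4 and Smad5 were higher, and Ctnnb1 (beta-catenin), Notch3, Hey1, Ptch1, Fzd7 and Bmpr1a were lower. Id2 had a log2 change of 2.30 ± 0.28 and Ctnnb1 of -1.46 ± 0.23 (SE, n = 2 per group). Of the chromatin regulators Ep400 and Arid1a, subunits of remodelling complexes, had -1.36 ± 0.35 and -1.27 ± 0.33, and Arid1b had 1.17 ± 0.34 (SE). None of these 5 genes with log2 values, nor Notch3, was called without either anti-m6A library (edgeR adjusted p from 0.0779 to 0.568), and Arid1b was not called with DESeq2's size factors (0.171). Both mitochondrial ribosomal RNAs were lower, but without either anti-m6A library neither mt-Rnr2 (edgeR adjusted p = 0.0789 and 0.0909) nor mt-Rnr1 (0.111 and 0.154) was called. Among markers of other cells, 5 and 5 of 15 blood, 3 and 3 of 9 endothelial, 3 and 3 of 9 pericyte and muscle, 1 and 0 of 3 osteoclast and 1 and 0 of 2 Schwann and neural transcripts were higher and lower. Adjusted over the list alone, the counts were 71 and 54 for Zfp genes, 1 and 3 for chromatin regulators, 6 and 5 for pathway genes, 6 and 5 for blood and 1 and 1 for osteoclasts. Median and mean differed in sign for pathway genes (0.30 and -0.01), blood (0.50 and -1.63), pericytes and muscle (-0.26 and 0.03) and osteoclasts (-1.06 and 1.58). Ramp2, a receptor-modifying protein of endothelium, rose by a log2 change of 4.78 ± 0.64 (SE; edgeR adjusted p = 0.00780), from 105 and 46 counts in Input to 1079 and 959. Rgs5, a pericyte marker, had 0 counts in Input and in IgG and 182 and 169 in anti-m6A, at least 124-fold above the Input floor, and was not called without anti-m6A replicate 1 (edgeR adjusted p = 0.0526).

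A transcript recovered by the m6A antibody beyond both background and abundance should be higher in anti-m6A than in IgG and in Input. Klf2, Igf1, Isg20, Son, Malat1, Fabp4 and Cebpb were among these genes (joint adjusted p of 0.0291 for Klf2, 0.0121 for Igf1 and 0.0112 for the others, from edgeR's one-sided tests). Of these, Malat1 lost its call against Input with DESeq2's size factors and with library totals (edgeR adjusted p = 0.253 and 0.332) and against IgG with library totals (0.0601). Igf1 lost its call against Input with library totals (edgeR adjusted p = 0.0614). The joint test called 2666 genes, of which 2317 had 0 counts in both IgG libraries and 1228 had 0 counts in both Input libraries. Of the 2666, 1200, Isg20 among them, had 0 counts in all IgG and Input libraries, so neither background nor abundance was detected for them. In each group 321 were detected, and 228 had at least 10 counts in each library. Genes called higher in each comparison separately numbered 2720, where independent lists of the same sizes would share 2308. Both comparisons share the anti-m6A libraries, so the lists are not independent. With the replicate number as a block the edgeR joint test called 0 genes, and 3264 had an unadjusted joint p under 0.05. The joint count was 1 without anti-m6A replicate 1, 1 without replicate 2 and 1 with the pairs summed. It was 190 among the 1757 genes with at least 10 counts in each library, 1675 without IgG replicate 1, 1875 without IgG replicate 2, 4135 without Input replicate 1 and 4497 without Input replicate 2.

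The comparison of IgG with Input was used as the background of the pull-down. It does not separate RNA held by the beads from RNA added during library making, and the source of the liver transcripts was not settled. The 5 largest increases in IgG were Agxt, Hpx (haemopexin, a plasma protein made in liver), Pcdhb21 (a protocadherin of a cluster of similar genes), Cyyr1 and Ppp1r12b (a myosin phosphatase subunit), each with 0 counts in Input; Agxt was at least 4352-fold and Hpx at least 3891-fold above the Input floor. The 5 largest decreases were Tubb5, Akr1a1 (an aldehyde reductase), Igf1, Copz2 and Sub1, each with 0 counts in IgG; Tubb5 was at least 604-fold lower. By edgeR's quasi-likelihood test 1116 genes were higher in IgG and 6941 were lower, 6080 of the latter with 0 counts in both IgG libraries. Among genes with at least 10 counts in each library the counts were 480 and 571.

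Of 15 blood transcripts 9 were higher in IgG than in Input and 4 (Csf1r, Ltf, Slc4a1 and Tyrobp) were lower; Camp, a neutrophil granule peptide, rose by a log2 change of 2.95 ± 0.25 (SE, n = 2 per group) and Hba-a2 by 2.81 ± 0.20. Relative to other genes this list was higher (camera adjusted p = 1.74e-06), with adjusted p = 0.553 with an estimated correlation. Replication-dependent histones (9 higher and 6 lower of 25, median 1.05), oxidative phosphorylation subunits (27 and 16 of 77, median 0.46, mean -0.99) and ribosomal proteins (17 and 20 of 84, median 0.07, mean -0.96) were also higher than other genes, most of which were missing from IgG. Their camera adjusted p values were 1.44e-06, 7.37e-11 and 1.77e-05, and with an estimated correlation the adjusted p values were 0.216, 0.566 and 0.566. With DESeq2's size factors the ribosomal median was -0.46 (camera adjusted p = 0.05004) and that of oxidative phosphorylation -0.024 (2.05e-06). Without IgG replicate 1 the ribosomal median was -0.25, that of oxidative phosphorylation 0.12 and that of histones -0.33; without Input replicate 2 the ribosomal median was -0.059, and without IgG replicate 2 the histone median was 0. Among genes with at least 10 counts in each library the ribosomal and oxidative phosphorylation medians were -0.68 and -0.27, and neither these lists nor the histones were called (camera adjusted p = 0.0753, 0.779 and 0.773). Adjusted over the list alone, 9 and 4 histones, 27 and 14 oxidative phosphorylation subunits and 14 and 19 ribosomal proteins were higher and lower. Of 15 cell cycle genes 3 were higher in IgG than in Input and 6 were lower, and of 22 m6A genes 1, Fto, was higher and 17 were lower. Among the higher ones Cdk1 and Top2a rose by 3.95 ± 0.37 and 1.86 ± 0.33, and Fto by 3.53 ± 0.39 (log2, SE). Of the 24 niche and progenitor genes 18 were lower in IgG and none was higher, and of 28 chromatin and transcription regulators 25 were lower and 2, Chd7 and Kmt2c, were higher.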

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

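The tests among genes with at least 10 counts in each library and with pull-down pairs summed were chosen after the result was seen. Counts of calls in IgG against Input, and in anti-m6A against IgG, stayed within 1.5 times of the reported ones under each alternative chosen before the data were examined. Genes lower in anti-m6A than in Input were 3635 by DESeq2. With an adjusted p of 0.01, 1982 genes were higher and 736 lower than in Input, and the edgeR joint test called 0, because its smallest adjusted p was 0.0112; 3449 genes had an unadjusted joint p under 0.05, and DESeq2 called 2420. At least 50 counts in 2 libraries gave 1706 joint genes from fewer genes tested. Leaving out 1 library gave 370 to 5152 genes higher and 72 to 3961 lower than in Input, and 1 to 4497 joint genes; a group left with 1 library is assumed to vary like the others. Fits without an anti-m6A library take the spread from the wider IgG and Input pairs, and fits without an Input library lose the widest pair.

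The replicate numbers are not stated to mark shared animals, and same-numbered libraries deviated together weakly (correlations across genes of 0.05 for Input and IgG, 0.10 for Input and anti-m6A and 0.14 for IgG and anti-m6A). With the replicate number as a block, 1242 genes were lower in anti-m6A than in Input and the edgeR joint test called 0, with 3264 at an unadjusted p under 0.05; the cause was not tested.

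Among genes with at least 10 counts in each library there were 593 genes higher and 586 lower in anti-m6A than in IgG, 410 and 518 than in Input, 480 and 571 in IgG than in Input, and 190 joint genes, from 1757 genes tested. There the median of ribosomal proteins was 0.75 in anti-m6A against IgG and -0.68 in IgG against Input, that of oxidative phosphorylation 1.03 and -0.27, and mt-Rnr2 was at -0.0215 in IgG against Input, each on the other side of its reported direction, for lists relative to other genes. In anti-m6A against IgG both lists were then called higher than other genes (camera adjusted p = 0.00725 and 0.00126); the comparison genes no longer include those missing from IgG. With pull-down pairs summed, where the spread comes from the Input pair alone, 5486 genes were higher and 572 lower in anti-m6A than in IgG, 711 and 174 than in Input, and 1 was joint; 882 of the 885 calls against Input among the genes of both fits were also calls of the same direction with all libraries. Of single-gene values under an alternative, 3431 kept their direction and side of the threshold, 216 lost and 75 gained a call and 1 reversed. Of list values, 749 kept them, 33 lost and 57 gained a call and 4 reversed; 41 of the 57 came from fry, which tests a list by itself and not against other genes. For counting error alone, 0 counts in the IgG libraries allow up to 1.16 and 1.94 CPM, but depth was not shown to be what keeps genes out of IgG.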

Other observations

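The tests of recovery without the antibody, of liver RNA and of the replicate pairs were chosen only after the result was seen; those of transcript length and DRACH motifs were written before it.

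The oxidative phosphorylation list, and with TMM scaling the ribosomal protein list, lay above other genes in anti-m6A against Input by camera with the preset correlation, for which a candidate explanation is transcript length. Random lists matched on length and mean expression had a median log2 change of 1.26 for oxidative phosphorylation (median length 875 nt). The list's own median lay at their percentile 80.6. For ribosomal proteins (914 nt) the random median was 1.23, and the list's median of 0.79 lay at percentile 0.93. Neither list exceeded genes of like length and mean expression. That mean is over all 6 libraries, anti-m6A included, and members of each list could enter the random lists of the other. The test therefore cannot separate length from abundance. Recovery without the antibody was first tested on genes found in both IgG libraries without matching. There the anti-m6A against IgG medians exceeded those of other genes by 1.11 for ribosomal proteins and 1.19 for oxidative phosphorylation. After this was seen, it was replaced by a test against lists matched on length and Input abundance, because presence in IgG rises with Input abundance. Whether presence in IgG depends on length was not tested. The matched median of ribosomal proteins (0.66) lay at percentile 99.98 of these lists, and that of oxidative phosphorylation (0.74) at percentile 88.4. The random lists held only genes found in both IgG libraries. Of genes with 1000 to 5000 Input counts 29.6% were found in both, against 80 of 84 ribosomal proteins. The matched genes were thus selected for counts in IgG, which lowers their anti-m6A against IgG change. For neither list can recovery without the antibody therefore be told apart from recovery by it. Collagens, at a median length of 5626.5 nt, lay at percentile 1.5 of their own matched lists. Replication-dependent histones (630 nt) lay at percentile 61.6, with a median of 2.28 against 1.92 for random lists of median length 816 nt. They thus did not exceed genes of roughly like length and mean expression. Chromatin and transcription regulators (9108 nt) lay at percentile 77.2.

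Hepatocyte transcripts were found in the libraries, although a sort for DsRed should remove hepatocytes. Of the 40 listed, 16 and 34 were detected in the Input libraries, and Alb had 114 and 1655 counts in Input, 5744 and 2833 in IgG and 374 and 282 in anti-m6A. A fixed trace of liver RNA added during library making, taking a larger share as less RNA is recovered, would leave both Input libraries lowest; 1 was, at 0.0365%, but the other held 0.456%, above both anti-m6A libraries, and with 1 library on each side this source cannot be told apart from others. Liver cells of the same P2 animals were tested as a source, for which counts of Afp, abundant in perinatal liver, would be predicted. Afp had 3 counts over the 6 libraries, 0.0273% of the 11002 counts of Alb, and 0 in both IgG libraries. Mup20, which the adult liver expresses, had 2754 and 1725 counts in IgG and 1540 in Input replicate 2. Both values point away from this source, but each is of 1 gene. Apob, Cps1 and Itih4 were at 0 in each library, so abundant liver transcripts can be missed here and this source cannot be told apart from others either; beyond such carry-over of cells, no biological explanation was tested.

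The pull-down replicates were closer than the Input replicates. Differences in depth as the reason are argued against, since at 20 to 200 counts the Input pair differed by 28.7 times random sampling and the anti-m6A pair by 2.61 times, a ratio of 11.01. The IgG pair differed by 8.78 times. Of genes with 200 to 1000 Input counts, 15.3% were found in both IgG libraries, where independent loss would give 3.03%, and 98.8% of those in replicate 2 were also in replicate 1. That each pull-down pair is 1 recovered RNA preparation made into 2 libraries remains a hypothesis, since the labels do not say. At 20 to 200 counts the anti-m6A pair lay under the bound of 5 times random sampling used for it, but the IgG pair lay above that value. At 200 to 1000 counts the anti-m6A pair differed by 6.10 times and the IgG pair by 23.3 times. At 1000 to 5000 counts the values were 19.6 and 24.9, and from 5000 counts 76.3 and 59.0. Genes shared by both IgG libraries cannot separate this from separate pull-downs that keep the same genes. In Input, 184 genes had over 500 counts in replicate 2 and under 5 in replicate 1, and 0 genes the reverse.

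A dependence of the anti-m6A against Input change on m6A sequence context was tested as a hypothesis. Across 10180 genes with a 3' UTR (90.2% of those tested), the partial Spearman correlation with DRACH motifs per kb of 3' UTR, given length and GC content, was 0.0219 ± 0.00992 (bootstrap SE), under the bound of 0.05 set in advance. The correlation with transcript length was -0.20. Genes are not independent replicates, and motif density says nothing of which motifs are methylated.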
